A study of Mus musculus with 24 samples.

How the data were processed

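The series holds mRNA sequencing of mouse liver, sampled every 4 h over 24 h of zeitgeber time (ZT, hours counted from lights on) from wild-type mice and from mice lacking the 3 PAR bZip transcription factors Dbp, Tef and Hlf, all fed ad libitum and aged 12 to 16 weeks per the labels. There were 24 libraries in 12 groups, 1 group for each genotype at each of 6 times, with 2 libraries per group. Replicate 1 of every group carries the letter I in the labels and replicate 2 the letter P, here called set I and set P. An M stands in the names of all 24 libraries. The labels do not say what these letters mean and do not spell out the sex of the mice or which exons of the 3 genes were deleted. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

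RNA was extracted with a guanidinium thiocyanate buffer and libraries were made with the TruSeq Stranded mRNA kit, per the labels' protocols. The authors deposited 1 table of raw read counts per Ensembl gene, not normalized, with 1 column per library. STAR 2.4.0i and the genome build mm10 are named in the submitters' processing notes. The counting tool, the gene annotation and the strand setting are not given in the sources used here. Counts of overlapping genes, of antisense partners and of near-identical gene copies could therefore have been split in ways that cannot be checked here. This concerns the Cyp2c, Cyp4a, Cyp3a, Mup, Saa, Klk, Hba and H2 families and ribosomal protein genes with processed copies.

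The table listed 54532 genes, of which 54409 matched a gene symbol in the GENCODE M21 annotation of the same build, which also supplied coordinates. All 24 columns were used. Transcript length and GC content came from the longest annotated transcript and were found for 15081 of the genes tested, or 99.94%. Totals ran from 14613001 to 19288322 counts per library. CPM values are counts over TMM-scaled library sizes from the cpm function of edgeR, computed here from the deposited counts. Intervals on counts cover counting error only, because the reads carry no molecular identifiers.

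All tests were edgeR 4.0.16 quasi-likelihood F-tests (R 4.3.3) on the counts as deposited. Library sizes were scaled with TMM and genes were kept with filterByExpr by group at its default minimum of 10 counts, which left 15090 genes. P-values were adjusted with the Benjamini-Hochberg method and called at an adjusted p under 0.05. For genotype, 1 fit of 12 group means used all 24 libraries, so that all groups shared 1 estimate of the spread. Knockout was compared with wild type as the mean over the 6 times and at each time. For rhythms, 1 fit held a cosine and a sine of a 24 h period for each genotype. Wild-type rhythm, knockout rhythm and the difference between them were each tested over both terms. The peak time and the amplitude, which is the log2 height of the fitted curve above its mean, came from the same fit. A genotype by time interaction was tested in the fit of group means.

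There were 42 gene lists written before the data were examined, for metabolic pathways, stress responses, protein complexes and the cell types a liver piece could hold. Of these, 39 had at least 5 measured members and were tested with camera (limma 3.58.1, preset correlation 0.01) on voom values. Camera compares a list with all other genes. It was repeated with a correlation estimated for each list. Fry, which tests a list against no change and not against other genes, was run beside it. Lists were also tested with Fisher's exact test for an excess of genes whose rhythm differed. The deleted factors (3 members), pancreatic acinar cells (2 of 16 members measured) and skeletal muscle (1 of 10) were not tested as lists.

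The rule for naming genes was also set before the data were examined. It takes the 3 deleted genes and all core clock genes. For the averaged contrast it takes the 10 largest rises and the 10 largest falls with a mean log2 CPM of at least 1 and the same sign at all 6 times. It takes up to 4 members per list with the smallest p. For each time it takes 3 rises and 3 falls with both knockout libraries beyond both wild-type libraries. For rhythms it takes the 6 smallest p in each genotype, and for the rhythm difference the 10 smallest with the larger amplitude in either genotype. Clone and gene model names, and names with the pseudogene ending -ps, were passed over. Other members of a list were named where 5 or fewer members rose or fell, and these, like the genes of the closing parts, were chosen after their values were seen. Some genes that the rule names are not reported here.

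Before calls were compared, libraries of the same letter were checked for common deviations from their group means. Across genes, the wild-type and knockout libraries of the same letter and time correlated at r of 0.298, 0.23, 0.332, 0.142, 0.158 and 0.145 from ZT04 to ZT24, all above the limit of 0.1 set for this. Over all pairs of groups, 62 of 66 lay above 0.1. The median r was 0.694 between wild-type groups, 0.247 between knockout groups and 0.232 across genotypes. The letter effect was thus mostly one of wild type, and a block common to both genotypes may fit it only in part. The letters were taken to pair the samples, and a fit with the letter as a block was the alternative for every result. The 2 libraries of a group differed by more than sampling noise in all 12 groups, with a mean chi-square per gene of 13.8 to 189 where sampling alone gives 1, so no pair was treated as 1 library.

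As an indirect sign of quality, the deviation of each library from the median of all libraries was set against GC content and log2 transcript length. This used 9970 genes with a mean log2 CPM of at least 2. RNA integrity itself was not measured here, so such a trend does not tell its cause. Genes are not independent replicates, so these r values describe a library and carry no test. Alternatives chosen before the data were examined were RLE factors, no filter, a mean CPM of at least 1, a threshold of 0.01, a robust prior, a tested fold of at least 1.5 (glmTreat), each set alone, the letter block, an additive fit, fits on fewer libraries, time as a factor, model choice by BIC, DESeq2 1.42.0 and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out the 3 wild-type set I libraries that followed GC content most, leaving out all 6 of set I in wild type, set P alone for the gene lists, and each library's slope on length as a covariate, with and without the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

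The tests were run on simulated counts with 200 changed genes, drawn from the real means and library sizes. Each gene was drawn independently, without the GC and length trends, the letter effect or any correlation between genes. The rates below may therefore not carry over to the real libraries. In the averaged contrast, 8% of genes changed 1.25-fold were recovered, 42% at 1.5-fold, 84% at 2-fold and 100% at 4-fold, and 4.1% of the calls were unchanged genes. For a single time (ZT12), none were recovered at 1.5-fold, 6% at 2-fold and 88% at 4-fold, and 11.3% of the calls were unchanged genes. A wild-type rhythm was recovered in 40% of genes at a peak to trough of 2-fold and in 94% at 4-fold. A rhythm present in 1 genotype was recovered as a difference in 2% of genes at 2-fold, 72% at 4-fold and 88% at 8-fold. Peak times of the 100 simulated genes with a peak to trough of at least 4-fold were off by a median of 0.26 h. Model choice by BIC called 1303 genes, of which 1148 were unchanged, so it served as an alternative and not as a result. DESeq2 called 12.7% to 18.7% unchanged genes in these simulations.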

Results

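Liver RNA was sequenced from wild-type mice and from mice without Dbp, Tef and Hlf, factors that are themselves driven by the circadian clock and act on its output genes. Samples were taken at ZT04, ZT08, ZT12, ZT16, ZT20 and ZT24, with 2 libraries per genotype and time and 24 in all. Counts per library totalled 17462026 to 19288322 in wild-type set I and 14613001 to 18068662 in wild-type set P. In the knockout they totalled 14959850 to 17410682 in set I and 14807940 to 17214706 in set P. Wild-type set I stood apart in its trend with GC content and transcript length, the cause of which was not tested. Across genes, its deviation from the median library followed GC content with a mean r of 0.501 ± 0.174 (SD, n = 6), against −0.0707 ± 0.143 in wild-type set P. The knockout means were −0.046 ± 0.0693 in set I and −0.3 ± 0.104 in set P (SD, n = 6 each). The highest values were those of wild-type set I at ZT04 (0.63), ZT16 (0.65) and ZT20 (0.685). These 6 libraries also counted short transcripts more, with r against log2 length between −0.394 and −0.15. Because they fall in a single genotype, counts in set P alone are given beside the gene groups below.

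**Figure D1:**
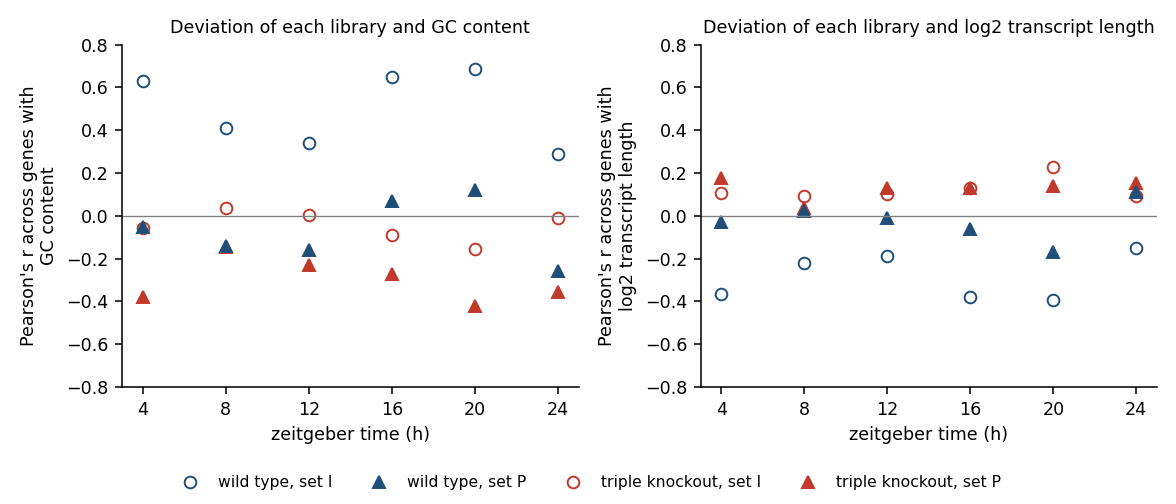
Correlation across genes (r) of each library's deviation from the median library with GC content and with log2 transcript length, by zeitgeber time in hours, with circles for set I, triangles for set P, blue for wild type and red for knockout. Wild-type set I lies above the other libraries for GC content, between 0.29 and 0.685.

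The deleted genes were compared first, since their loss is what separates the genotypes. Dbp (ENSMUSG00000059824, mm10 chromosome 7, 45705088 to 45710203, plus strand) averaged 15.4 ± 20.3 CPM in wild type and 0.0199 ± 0.0383 CPM in the knockout (SD, n = 12 each), where all 12 libraries together held 4 counts. Hlf (ENSMUSG00000003949, chromosome 11, 90336536 to 90390895) averaged 72.7 ± 18.1 against 1.55 ± 1.02 CPM, a 46.9-fold lower mean. Tef (ENSMUSG00000022389, chromosome 15, 81802421 to 81826863) kept the most counts, with 185 ± 103 against 14.7 ± 9.82 CPM, a 12.6-fold lower mean. For each of the 3 genes the 12 knockout libraries lay below the 12 wild-type libraries. All are protein coding, and counts per exon were not used here, so which parts of Tef and Hlf were still transcribed is not known. The log2 changes averaged over the day were −5.88 for Hlf (SE 0.13, edgeR adjusted p = 1.92e-13) and −3.71 for Tef (SE 0.12, edgeR adjusted p = 1.12e-11).

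**Figure D2:**
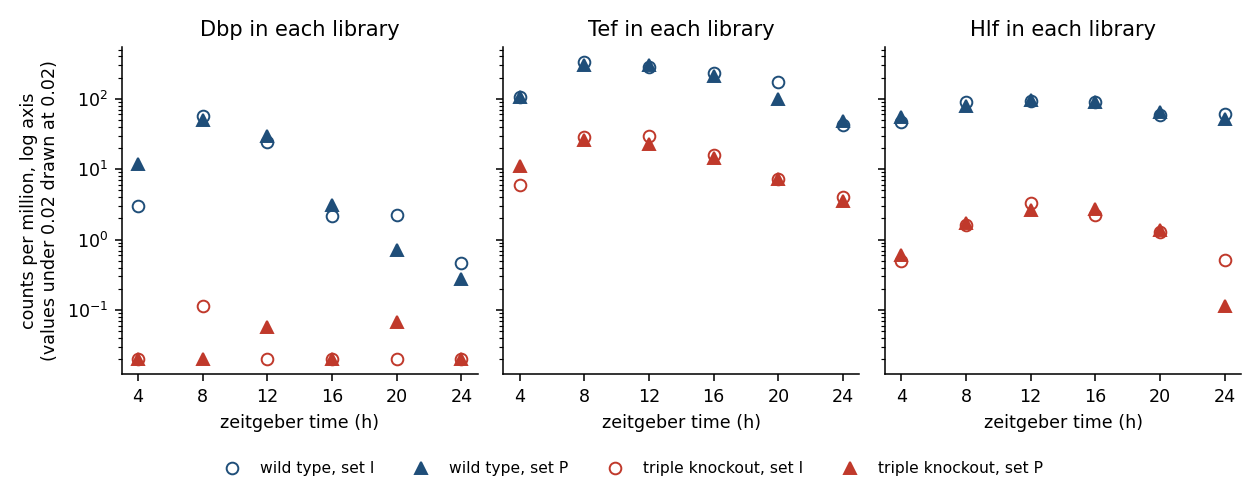
CPM of Dbp, Tef and Hlf in each library on a log axis, by zeitgeber time in hours, for wild type (blue) and knockout (red), with values under 0.02 drawn at 0.02. All knockout libraries lie below all wild-type libraries for each gene.

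The averaged contrast asked which liver genes differed between genotypes over the whole day. The deepest falls were in Nlrp12, Cyp4a10 and the Cyp2c genes. Nlrp12, a NOD-like receptor gene (chromosome 7, 3218784 to 3249740), went from 69.1 ± 31.9 to 0.476 ± 0.289 CPM (SD, n = 12, log2 change −7.24, SE 0.27, edgeR adjusted p = 7.41e-11). Cyp4a10, a fatty acid omega-hydroxylase (chromosome 4, 115518264 to 115533649), went from 477 ± 427 to 8.41 ± 9.16 CPM (−5.83, SE 0.32, edgeR adjusted p = 7.5e-09). Cyp2c50 (chromosome 19, 40089688 to 40113950) went from 659 ± 61.4 to 21.4 ± 7.05 CPM (−4.97, SE 0.15, edgeR adjusted p = 3.82e-12), and its neighbours Cyp2c54 and Cyp2c37 fell with log2 changes of −4.93 and −3.33. Cyp2b10, a target of the receptor CAR, fell from 35.8 ± 35.9 to 1.5 ± 1.02 CPM. The other genes among the 10 deepest falls were Ttc39a (−3.92), Caln1 (−3.60), Pcp4l1 (−3.47) and Ppp1r1b (−3.44, within 10 Mb of Hlf).

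Among the 10 largest rises, Tmc5, a transmembrane channel-like gene (chromosome 7, 118597297 to 118675086), went from 0.921 ± 1.15 to 12.1 ± 3.26 CPM (SD, n = 12), with a ratio of means of 13.1 (edgeR adjusted p = 1.34e-07). Selenbp2, a selenium-binding protein gene (chromosome 3, 94693556 to 94704413), rose from 63.7 ± 34.8 to 533 ± 271 CPM (log2 change 3.02, SE 0.17, edgeR adjusted p = 8.65e-09). Saa1, which encodes the acute-phase protein serum amyloid A, rose from 330 ± 606 to 1683 ± 732 CPM (3.10, SE 0.42), with 2220 CPM in wild-type ZT08 replicate 2. Tead2, a transcription factor of the Hippo pathway, rose from 0.837 ± 0.252 to 7.77 ± 2.08 CPM (3.20, SE 0.12), and Slc6a16 rose from 1.04 ± 0.343 to 10.5 ± 4.23 CPM (3.31). Saa1, Tead2 and Slc6a16 lie within 10 Mb of Dbp on chromosome 7. Moxd1 averaged 8.61 ± 17.8 and 86.5 ± 91.6 CPM (log2 change 4.11, edgeR adjusted p = 0.0239), but its call was lost without any of 7 of the 24 single libraries (edgeR adjusted p 0.0522 to 0.316). Igsf23 (3.0), Synm (2.97) and H2-Bl (2.54) were also among the rises. Rpl3-ps1, whose rise is given below, was passed over by the rule for naming genes.

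**Figure D3:**
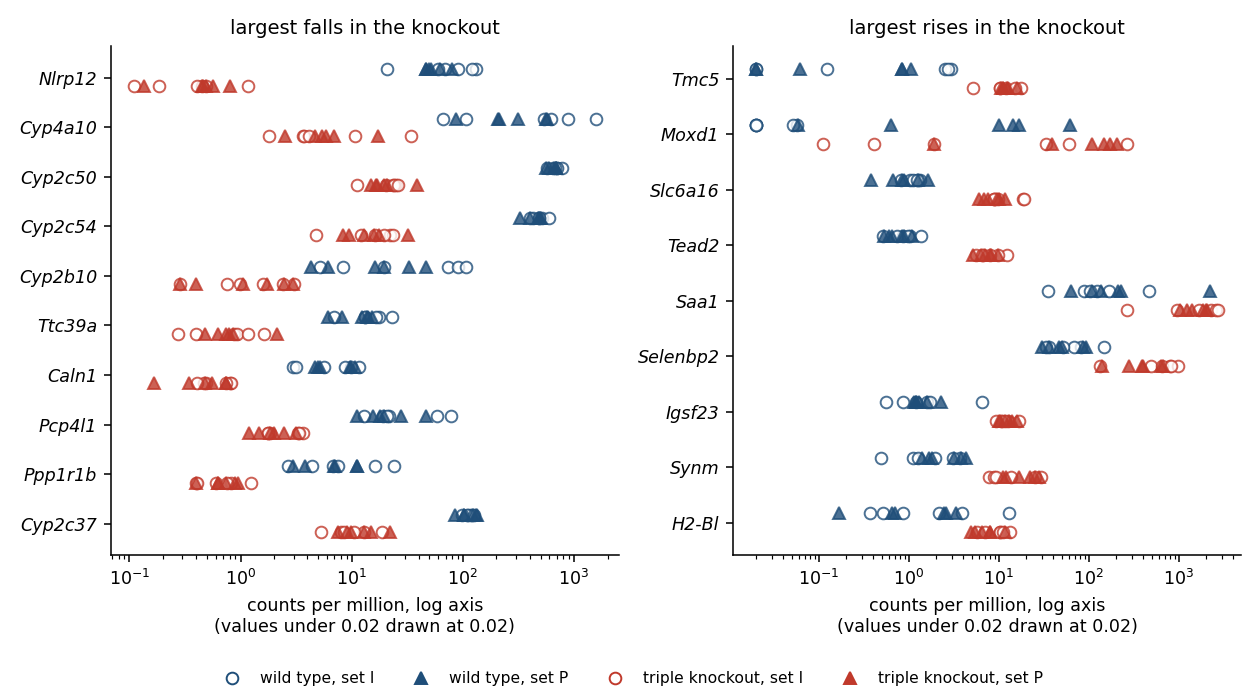
CPM per library, on a log axis, of the 10 largest falls and of 9 of the largest rises averaged over the day, for wild type (blue) and knockout (red). Nlrp12 lies at a mean of 69.1 CPM in wild type and 0.476 CPM in the knockout, and Selenbp2 at 63.7 and 533 CPM.

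Enzymes that handle drugs and other foreign compounds were the group PAR bZip factors are best known to drive. Of 27 measured P450 genes of drug metabolism, 9 fell, 3 rose and 15 did not pass (3 up and 9 down adjusted over the list alone, 3 up and 8 down in set P). Besides the Cyp2c genes and Cyp2b10, the list held rises in Cyp3a59 (104 to 175 CPM), Cyp3a25 (835 to 1263 CPM) and Cyp2c40, which stayed under 1 CPM. The list as a whole shifted down (camera adjusted p = 0.0124), with an adjusted p = 0.596 with an estimated correlation. With the letter block and the length slope of each library together, the camera adjusted p was 0.0549. Carboxylesterases and other phase I enzymes fell in 14 of 25 genes and rose in Aox1 (0.69) and Aox3 (1.15), with 2 up and 15 down adjusted over the list alone and 2 up and 9 down in set P. Ces1g fell from 117 ± 51.9 to 18 ± 11.7 CPM (SD, n = 12, log2 change −2.87, SE 0.18), Ces1d from 1124 ± 689 to 299 ± 147 CPM (−1.83, SE 0.12) and the retinal dehydrogenase gene Aldh1a1 from 1623 ± 232 to 706 ± 122 CPM (−1.21, SE 0.08). This list had a camera adjusted p = 0.000114, and an adjusted p = 0.596 with an estimated correlation.

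Of 13 partners of P450 enzymes and genes of heme supply, 4 fell (Por, Cpox, Urod and Fech) and 2 rose (Cyb5b and Pgrmc1), the same counts adjusted over the list alone (camera adjusted p = 0.282), with 0 up and 2 down in set P by edgeR. Por, the reductase that passes electrons to P450 enzymes, fell from 525 ± 375 to 288 ± 161 CPM (SD, n = 12, −0.80, SE 0.13). Conjugating phase II enzymes went both ways, with 9 of 38 lower, among them Gsta3 (−0.93), Gstt1 (−0.94) and Gsta2 (−1.19), and 6 higher, among them Ugt1a6a (0.70). Adjusted over the list alone, 6 rose and 10 fell (camera adjusted p = 0.489), and in set P 7 rose and 5 fell. Of 20 drug and metabolite transporters, 6 rose and 4 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.279). Abcc6, within 10 Mb of Dbp, rose from 138 ± 17 to 299 ± 41.4 CPM (1.11, SE 0.08), Slco1a4 from 79.3 ± 42.5 to 188 ± 49.4 CPM (1.29, SE 0.28) and Abcb1a from 2.97 ± 1.85 to 7.66 ± 2.49 CPM (1.49, SE 0.24). Abcg2 (−0.82), Slc22a7 (−1.18), Slc22a5 (−0.39) and Abcc3 (−0.41) fell. In set P alone the transporters shifted up (6 higher, 1 lower, camera adjusted p = 0.0267), with an adjusted p = 0.71 with an estimated correlation. Of 21 nuclear receptor genes, Nr1i3, which encodes CAR, fell from 54.4 ± 14.2 to 27.7 ± 6.6 CPM (−0.97, SE 0.12), as did Hnf4a (−0.35), Nr1i2 (−0.37), Nr1h3 (−0.38) and Rxrb (−0.38). There were 3 rises, among them Pparg (0.50) and Ahr (0.68), and adjusted over the list alone the counts were again 3 and 5, while in set P 4 rose and 1 fell. The median of this list was −0.13, its mean 0.09 and its camera direction down (camera adjusted p = 0.766).

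Lipid and amino acid metabolism followed. PPAR-alpha targets and fatty acid oxidation genes fell in 26 of 39 cases (28 adjusted over the list alone, 16 in set P, where 2 rose), and Fabp1 (0.38), Cd36 (1.06) and Vnn1 (0.41) rose. Cyp4a31 fell from 26.4 ± 31.8 to 4.23 ± 2.59 CPM (SD, n = 12, −2.31, SE 0.24) and the acyl-CoA thioesterase genes Acot1 and Acot3 by log2 changes of −1.55 and −2.52. The list had a camera adjusted p = 1.72e-07, and an adjusted p = 0.596 with an estimated correlation. Amino acid and urea cycle enzymes fell in 21 of 32 cases and rose in Kmo (0.37), the same counts adjusted over the list alone, with 1 up and 14 down in set P. Oat fell from 774 ± 198 to 418 ± 122 CPM (−0.90, SE 0.09), Mat1a from 4879 ± 1994 to 2877 ± 684 CPM (−0.72, SE 0.12) and Agxt from 310 ± 89.9 to 195 ± 54.6 CPM (−0.68, SE 0.11). This list had a camera adjusted p = 1.51e-05, and an adjusted p = 0.596 with an estimated correlation. Of 14 bile acid synthesis genes, 7 fell and 2 rose (3 up and 8 down adjusted over the list alone, 1 up and 2 down in set P, camera adjusted p = 0.163). Slc27a5 fell from 1317 ± 447 to 587 ± 35.3 CPM (−1.14, SE 0.13), Cyp39a1 by −1.49 and Cyp8b1 by −0.98, whereas Cyp7a1, the rate-limiting enzyme, rose by 1.18 and Scp2 by 0.28.

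Cholesterol synthesis and uptake genes rose in 4 of 26 cases (Hmgcs1, Sc5d, Cyp51 and Stard4) and fell in 3 (among them Srebf2 and Ebp), with 3 and 3 adjusted over the list alone (camera adjusted p = 0.474). Hmgcs1, the entry step of the pathway, rose from 293 ± 141 to 796 ± 364 CPM (SD, n = 12, 1.45, SE 0.32). In set P alone 16 rose and 1 fell (camera adjusted p = 9.2e-08, adjusted p = 0.71 with an estimated correlation), and without all 6 wild-type set I libraries the camera adjusted p was 0.0405. Fatty acid and triglyceride synthesis genes fell in 6 of 29 cases, among them Elovl5 (−0.81), Fads2 (−0.58) and Dgat1 (−0.55), and Me1 rose (0.61), the same counts adjusted over the list alone (camera adjusted p = 0.541). In set P the direction was the other one, with 6 up and 3 down and a median of 0.17 (camera adjusted p = 0.115). In gluconeogenesis and glycogen, 8 of 22 genes fell and 3 rose, the same counts adjusted over the list alone (camera adjusted p = 0.406), while in set P 3 rose and 1 fell. The glycogen branching enzyme gene Gbe1 (88.1 ± 26.1 to 175 ± 23.6 CPM, log2 change 1.0) rose with Slc2a2 (0.45), and Igfbp1 fell from 47.1 ± 31.9 to 21.3 ± 17.4 CPM (−1.18).

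Liver secretory and stress genes were taken next. Of 27 acute phase genes, 7 rose and 6 fell (8 and 7 adjusted over the list alone, 5 and 2 in set P, median −0.02, mean 0.10, camera direction up, camera adjusted p = 0.766). Saa3, within 10 Mb of Dbp, rose from 5.89 ± 1.96 to 32.5 ± 10.7 CPM (SD, n = 12, 2.46, SE 0.17), and Hamp, which encodes the iron hormone hepcidin, fell from 400.4 ± 205 to 62.6 ± 36.7 CPM (−2.84, SE 0.25). Of 29 interferon response genes, Oas2 and Rsad2 rose and Bst2, Irf9 and Usp18 fell, and none passed adjusted over the list alone (camera adjusted p = 0.541). In set P alone 2 rose and 0 fell by edgeR, and the list shifted up (camera adjusted p = 0.00259, adjusted p = 0.769 with an estimated correlation). The Oas2 call was lost without wild-type ZT16 replicate 1, knockout ZT12 replicate 1 or knockout ZT20 replicate 1 (edgeR adjusted p 0.0511 to 0.0538), and those of Bst2, Irf9 and Usp18 without any of 13, 15 and 18 single libraries (0.0501 to 0.103). In the unfolded protein and amino acid stress response, 13 of 22 genes fell and 9 did not pass (the same adjusted over the list alone, 0 up and 2 down in set P by edgeR). Herpud1 (−0.64), Atf4 (−0.50), Trib3 (−0.69) and Atf5 (−0.66, within 10 Mb of Dbp) were among them. The camera adjusted p was 0.00975 with all libraries and 0.138 in set P alone, and adjusted p = 0.596 with an estimated correlation.

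Heat shock genes fell in 6 of 17 cases, among them the chaperone Hspa8 (−0.45), and Hspb1 rose (0.99), the same counts adjusted over the list alone, but in set P 1 rose and 0 fell by edgeR (median 0.02). The median of this list was −0.12 and its mean 0.05 (camera direction down, camera adjusted p = 0.724), and its call for Bag3 (−0.40) was lost without any of 14 single libraries (edgeR adjusted p 0.0546 to 0.0942). Of 19 immediate early genes 8 fell (9 adjusted over the list alone, 0 in set P by edgeR), including Myc (12.5 ± 14 to 6.03 ± 4.52 CPM, SD, n = 12, −0.96) and Atf3 (−0.78). The list passed without wild-type ZT12 replicate 2 (camera adjusted p = 0.0257, against 0.0911 with all libraries and an adjusted p = 0.633 with an estimated correlation). Dusp1 (−0.42) was lost without wild-type ZT04 or ZT16 replicate 1 (edgeR adjusted p 0.0513 and 0.0521) and Nr4a1 (−0.73) without wild-type ZT16 or knockout ZT20 replicate 1 (0.0606 and 0.0508). NRF2 targets fell in 5 of 22 cases (Gsta2, Osgin1, Ephx1, Gsr and Cbr1) and rose in Ugdh (0.73) and Me1, the same adjusted over the list alone, with 3 up and 2 down in set P (camera adjusted p = 0.474). Of 24 cell cycle genes Ccnd1 fell (−0.93) and Aurka rose (0.42), also adjusted over the list alone, with 1 up and 0 down in set P by edgeR (median −0.00, mean 0.08, camera direction up, camera adjusted p = 0.766).

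Sex-biased liver genes were listed beforehand because the labels do not state a sex. Of 25 male-biased genes Selenbp2, Mup20 and Moxd1 rose and Cyp2d9 (−0.69) and Ugt2b1 (−0.34) fell, with 3 up and 1 down adjusted over the list alone and 5 up and 4 down in set P (camera adjusted p = 0.489). Mup20 went from 445 ± 256 to 1028 ± 437 CPM (SD, n = 12, 1.23), and its call was lost without knockout ZT20 replicate 2 (edgeR adjusted p = 0.0544). Of 18 female-biased genes 4 fell, among them Acot3, Acot4 (−0.87) and Fmo2 (−0.92). The 5 that rose were Slc22a29 (1.92), Atp6v0d2 (0.98), Sult3a1 (2.17), Slc22a27 (1.26) and Cyp2c40 (0.63), with 5 up and 5 down adjusted over the list alone and 2 up and 3 down in set P (camera adjusted p = 0.766). The averaged change weighs each time equally, and Slc22a27 had mean levels of 2.22 and 2.02 CPM in wild type and knockout.

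Protein complexes present in all cells were compared in the same way. Of 82 cytosolic ribosomal protein genes, 47 fell and 3 rose (57 down and 3 up adjusted over the list alone, 15 down and 3 up in set P). Rpl3 fell from 264 ± 46.8 to 142 ± 12.4 CPM (SD, n = 12, −0.89, SE 0.08) and Rps15a from 133 ± 17.7 to 97.9 ± 7.32 CPM (−0.43, SE 0.07), while Rpl29 rose from 16.3 ± 4.93 to 54.9 ± 15.2 CPM (1.74, SE 0.15) with Rpl30 (0.37) and Rps3a1 (0.38). Rpl3-ps1, a processed copy outside the list, rose from 1.88 ± 0.314 to 33.8 ± 2.14 CPM (4.17, SE 0.09). Counts of Rpl3 and this copy could have been split differently in the 2 genotypes, which cannot be checked here. The fall of Rpl3 may therefore in part not be one of expression. Of 78 nuclear genes of the respiratory chain and ATP synthase, 58 fell and Cox6b2 rose (2 up and 61 down adjusted over the list alone, 1 up and 25 down in set P), for example Ndufc2 (−0.53) and Ndufa6 (−0.47). Cox6b2 went from 0.7 ± 1.32 to 5.28 ± 1.86 CPM (4.0, SE 0.28). The camera adjusted p was 9.52e-08 for the ribosomal list and 3.15e-10 for the respiratory list, with adjusted p = 0.633 and 0.596 with an estimated correlation. The ribosomal call ended with the letter block and length slope together (camera adjusted p = 0.525). Among the 10 respiratory genes of the mitochondrial genome mt-Nd1 fell (−0.28), also adjusted over the list alone, and 0 passed in set P by edgeR (camera adjusted p = 0.766). Of 38 proteasome genes 19 fell, among them Psmd9 (−0.50) and Psma7 (−0.46), and Psma3 rose (0.18), with 3 up and 20 down adjusted over the list alone and 2 up and 3 down in set P. The proteasome list had a camera adjusted p = 0.0281, against 0.334 in set P alone, and an adjusted p = 0.659 with an estimated correlation.

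Hepatocyte zones and other liver cell types were read from marker genes. Pericentral markers fell in 11 of 20 cases, among them Oat, Lhpp (−0.92) and Slc22a3 (−0.92), and Slc1a2 rose (0.61). The counts were 2 up and 11 down adjusted over the list alone and 2 up and 6 down in set P (camera adjusted p = 0.00855, adjusted p = 0.596 with an estimated correlation). Periportal markers fell in 6 of 18 cases, the same adjusted over the list alone, with 0 up and 8 down in set P by edgeR. Alb, which encodes serum albumin, fell from 62610 ± 8170 to 35380 ± 7323 CPM (SD, n = 12, −0.84, SE 0.11), with Ass1 (−0.57) and Tat (−0.47). The periportal list had a camera adjusted p = 0.0282 (adjusted p = 0.596 with an estimated correlation), and its call was lost without wild-type ZT08 replicate 2 (0.0507) or knockout ZT16 replicate 2 (0.0592). With genes of a mean CPM of at least 1 the periportal and proteasome calls were both lost (camera adjusted p = 0.0558 each). With each library's length slope as a covariate the camera adjusted p was 0.264 for pericentral, 0.178 for periportal and 0.711 for proteasome genes, and with the block added the proteasome direction turned up (0.753).

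Of 14 Kupffer cell and macrophage markers, Adgre1 (0.45), Marco (0.76), Cd163 (0.53), Vsig4 (0.27) and Fcna (0.25) rose and 9 did not pass, the same adjusted over the list alone (camera adjusted p = 0.314). In set P alone 3 rose and 0 fell by edgeR, and the list shifted up (camera adjusted p = 0.00182, adjusted p = 0.71 with an estimated correlation). Vsig4 was lost without any of 9 single libraries (edgeR adjusted p 0.0508 to 0.0627) and Fcna without wild-type ZT12 replicates 1 and 2, wild-type ZT24 replicate 2 or knockout ZT20 replicate 2, each left out alone (0.0556 to 0.0636). Monocyte and dendritic cell markers fell in 6 of 13 cases, the same adjusted over the list alone, with the antigen-presentation genes H2-Ab1 (88 ± 16.6 to 47.2 ± 15.3 CPM, SD, n = 12, −0.93), H2-Aa (−0.87) and Cd74 (−0.69). That list passed without wild-type ZT24 replicate 1 (camera adjusted p = 0.0425) or knockout ZT08 replicate 2 (0.0483), against 0.0969 with all libraries and 0.00677 in set P alone (0 up and 5 down by edgeR). It had an adjusted p = 0.633 with an estimated correlation with all libraries and 0.71 in set P. B and plasma cell markers fell in 6 of 12 cases (7 adjusted over the list alone, 0 in set P by edgeR), among them Igkc (−0.51), Cd79a (−0.97) and Cd79b (−0.90). The list passed without wild-type ZT12 replicate 1 (camera adjusted p = 0.0367, against 0.101) and in set P alone (0.0339), with an adjusted p = 0.596 with an estimated correlation with all libraries and 0.743 in set P. Of 7 erythroid markers 2 rose, among them the globin gene Hbb-bs (0.46), also adjusted over the list alone, with 2 up and 0 down in set P by edgeR. Hbb-bs was lost without any of 12 single libraries (edgeR adjusted p 0.0542 to 0.0865), and the list passed without knockout ZT20 replicate 1 (camera adjusted p = 0.0421, against 0.238) and in set P alone (0.0424), with an adjusted p = 0.795 with an estimated correlation with all libraries and 0.726 in set P.

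Of 15 sinusoidal endothelial markers Ptprb (0.62) and Kdr (0.24) rose, none adjusted over the list alone, with 1 up and 1 down in set P (camera adjusted p = 0.569). The list passed, upward, with each library's length slope as a covariate (camera adjusted p = 0.0362, adjusted p = 0.927 with an estimated correlation with all libraries). With that covariate the Kupffer (0.00417), erythroid (0.0358) and cholesterol lists (0.0202) also passed upward, and the monocyte (0.00731), B cell (0.046) and clock output lists (0.0358) downward. Their adjusted p with an estimated correlation with all libraries was 0.596 to 0.927. Ptprb was lost without wild-type replicate 1 of ZT04, ZT08, ZT16 or ZT24 (edgeR adjusted p 0.0503 to 0.0568) and Kdr without any of 20 single libraries (0.051 to 0.0978). Of 17 stellate cell and fibroblast markers Col1a2 (−0.45), Hand2 (−0.53), Colec11 (−0.25) and Acta2 (−0.52) fell and Reln (0.21) rose, also adjusted over the list alone, with 1 up and 0 down in set P by edgeR (camera adjusted p = 0.326). Hand2, Colec11 and Acta2 were lost without any of 2, 4 and 12 single libraries (edgeR adjusted p 0.0504 to 0.0898), those for Hand2 being wild-type ZT20 and ZT24 replicate 1. Of 8 cholangiocyte markers Sox9 (0.48) rose and Krt19 (−0.51) fell, with 2 and 2 adjusted over the list alone and 0 in set P by edgeR (median −0.16, mean −0.01, camera direction up, camera adjusted p = 0.949), and both were lost without any of 10 and 18 single libraries (edgeR adjusted p 0.0502 to 0.122). Of 15 T and NK cell markers Nkg7 (−1.82, within 10 Mb of Dbp) fell and Cd8a (0.95) rose, also adjusted over the list alone, with 1 up and 1 down in set P (camera adjusted p = 0.897). Of 10 neutrophil markers Cxcr2 rose and Ngp and Mpo (within 10 Mb of Hlf) fell, also adjusted over the list alone (0 up and 1 down in set P by edgeR). The neutrophil list had a median of 0.18, a mean of −0.39 and camera direction up (camera adjusted p = 0.836). Those calls were lost without knockout ZT20 replicate 2 for Cxcr2 (edgeR adjusted p = 0.055) and without any of 3 and 14 single libraries for Ngp and Mpo (0.051 to 1). Wild-type ZT08 replicate 2 held 9.6 CPM of Ngp and 2.91 CPM of Mpo, against at most 0.828 and 0.303 CPM in the other wild-type set P libraries, and both genes stayed called without it. Of 6 adipocyte markers Car3 (−0.72), a gene hepatocytes also express, and Plin4 (−0.52) fell, also adjusted over the list alone, with 0 up and 1 down in set P by edgeR (camera adjusted p = 0.406), and Plin4 was lost without any of 15 single libraries (0.0526 to 0.0982). Pancreatic acinar and skeletal muscle markers had 2 and 1 measured members and were not tested.

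**Figure D4:**
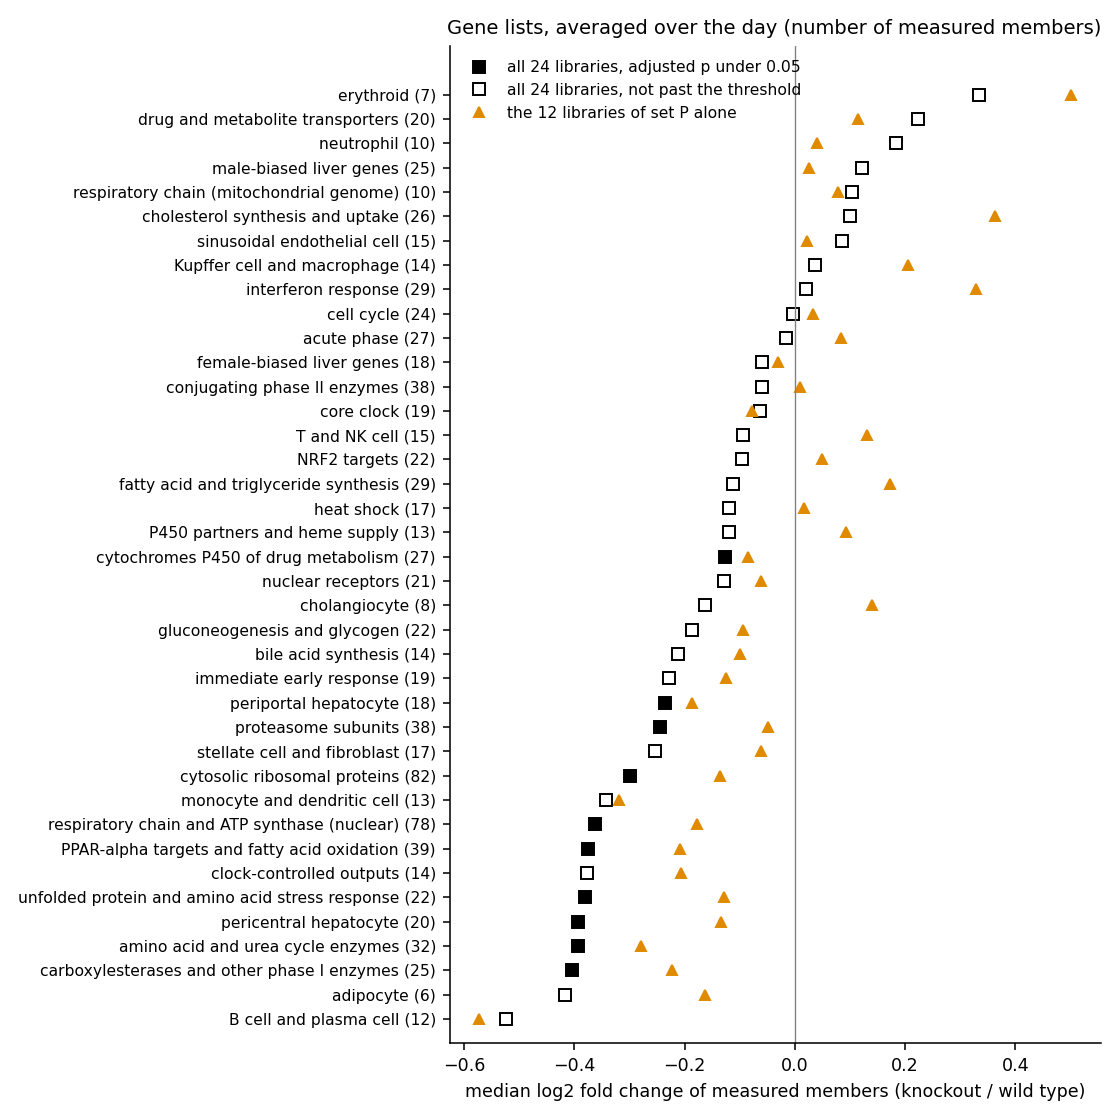
Median log2 change between knockout and wild type of each gene list, with all 24 libraries (squares, filled where the camera adjusted p was under 0.05) and in set P alone (orange triangles). All 10 filled lists lie below 0, from −0.13 for the P450 genes to −0.41 for the carboxylesterases.

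In total 5007 of 15090 genes differed between genotypes averaged over the day (edgeR quasi-likelihood, 24 libraries), 1827 higher and 3180 lower in the knockout, so 63.5% of calls were falls. Set P alone called 1963 genes, 1011 higher and 952 lower, of which 1535 were shared with the same sign and 0 with the opposite sign. Set P is part of the 24 libraries, so this agreement in sign is no independent replication. Without the 3 wild-type set I libraries that followed GC content most the count was 3295 (1582 higher, 1713 lower), and blocked by letter it was 7898. It rose to 7892, 7683 and 9084 without replicate 2 of wild-type ZT04, ZT16 and ZT20, and was 3359 without replicate 1 of wild-type ZT16.

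The core clock was compared because the deleted factors lie downstream of it. Of 19 clock genes, 6 fell and 1 rose averaged over the day (7 and 1 adjusted over the list alone, 4 and 1 in set P, camera adjusted p = 0.724). The period gene Per3 fell from 30.8 ± 29.8 to 11 ± 10.7 CPM (SD, n = 12, −1.35, SE 0.25), the repressor Cry1 from 40.7 ± 31 to 25.2 ± 17.4 CPM (−0.64, SE 0.11) and Nfil3, which competes with PAR bZip factors for their sites, from 36.3 ± 19.8 to 26.2 ± 17.1 CPM (−0.58, SE 0.11). Csnk1e, a kinase of the period proteins, rose from 7.34 ± 1.23 to 9.52 ± 0.765 CPM (0.38, SE 0.07). Ciart (−0.61) was lost without wild-type ZT24 replicate 1 (edgeR adjusted p = 0.0507), and Arntl (−0.35) and Cry2 (−0.31) without any of 7 and 12 single libraries (0.0509 to 0.072). The changes of Per1 (−0.03), Per2 (−0.06), Nr1d1 (0.56), Nr1d2 (0.40), Clock (0.72), Rora (0.59), Npas2, Bhlhe40, Bhlhe41 and Csnk1d did not pass. With each library's length slope as a covariate, Clock and Rora turned down (−0.35 and −0.37, edgeR adjusted p 0.0329 and 0.0031). Nr1d1, Clock, Rora, Bhlhe41 and Csnk1d would each pass without some single library, 5, 3, 1, 3 and 3 of them in that order (edgeR adjusted p 0.00975 to 0.0496). Of 14 clock-controlled output genes 7 fell and Tfrc rose (1.42), the same adjusted over the list alone, with 1 up and 4 down in set P. Mthfd1l (−1.32), Usp2 (−1.07) and Wee1 (−0.50) were lower, and Cdkn1a (−0.82) was lost without replicate 1 of wild-type ZT04, ZT08, ZT12, ZT16 or ZT24 (edgeR adjusted p 0.0567 to 0.0628). The output list passed without wild-type ZT04 replicate 1 (camera adjusted p = 0.0477, against 0.0911 with all libraries and an adjusted p = 0.596 with an estimated correlation).

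**Figure D5:**
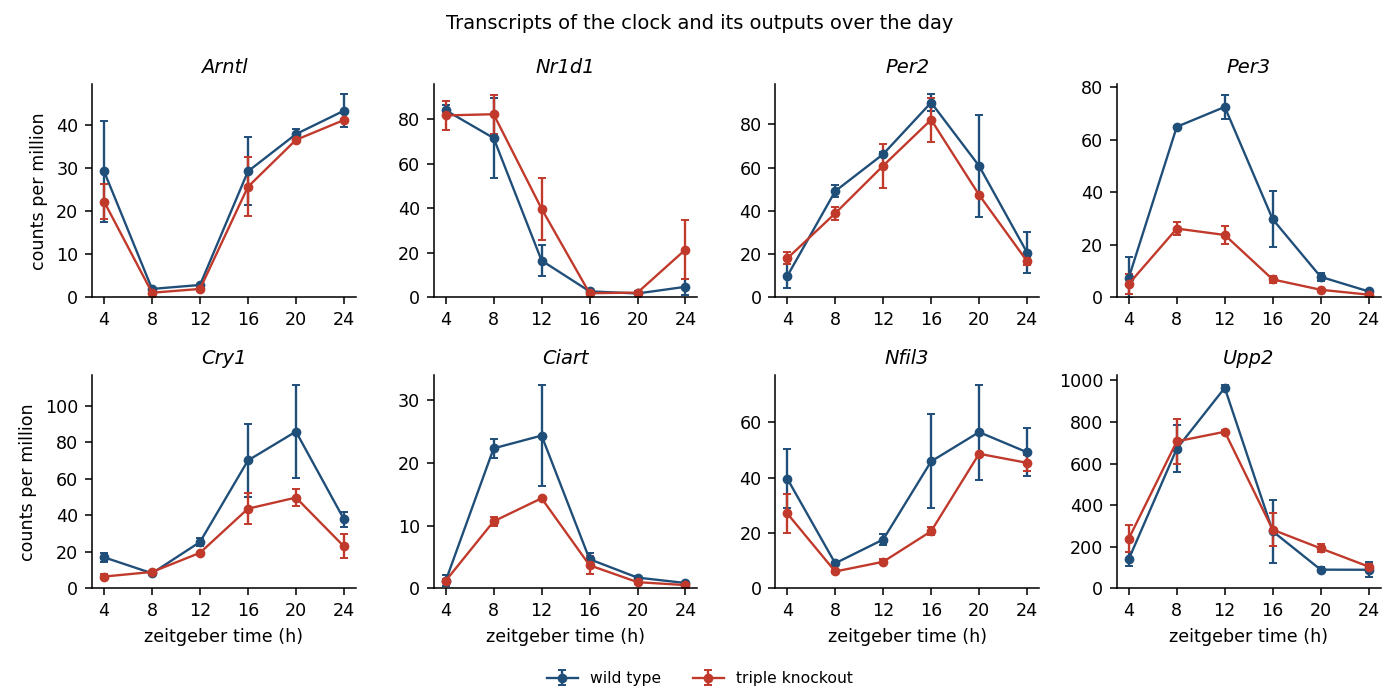
Mean CPM of Arntl, Nr1d1, Per2, Per3, Cry1, Ciart, Nfil3 and Upp2 by zeitgeber time in hours for wild type (blue) and knockout (red), with error bars of 1 SD between replicates (n = 2). Per3 averages 30.8 CPM in wild type and 11 CPM in the knockout.

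Each time was then tested by itself, with the same fit and n = 2 per group, to see which genes differed at that hour. At ZT04 the liver gene Selenbp2 rose from 35.8 ± 0.113 to 598 ± 296 CPM (SD, n = 2, log2 change 4.06, SE 0.43, edgeR adjusted p = 0.000117) and Tmc5 stood at 0.061 ± 0.0862 against 14.6 ± 4.68 CPM. Nlrp12 (−7.60, SE 0.66) and Cyp4a10 (−6.80, SE 0.81) fell, and 6 of 39 PPAR-alpha targets were lower. Synm (3.38) was lost without wild-type replicate 1 or knockout replicate 2 of ZT04 (edgeR adjusted p 0.0581 and 0.109). The ribosomal RNA gene n-R5-8s1 (−7.44), with 230 and 7.62 CPM in wild-type replicates 2 and 1, was lost without wild-type replicate 2 or either knockout replicate (0.085 to 0.321). In all 85 genes rose and 105 fell (190), or 370 blocked by letter. The count was 68, 41 and 64 without wild-type replicate 1, knockout replicate 1 and knockout replicate 2 of ZT04, 350 without wild-type replicate 2, and 399 and 353 without replicates 1 and 2 of wild-type ZT20.

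At ZT08 Selenbp2 (64.5 ± 25.8 to 803 ± 238 CPM, SD, n = 2, 3.64), Igsf23 (3.36) and Tead2 (3.21) rose. Nlrp12 (−6.51), Cyp2c54 (376 ± 68.7 to 6.59 ± 2.57 CPM, −5.83) and Cyp2c50 (−5.57, SE 0.37, edgeR adjusted p = 5.35e-07) fell, as did 4 of 27 P450 genes and 3 of 20 pericentral markers. In all 50 genes rose and 91 fell (141). The count was 47 without wild-type replicate 1, 46 without knockout replicate 1 and 73 without knockout replicate 2 of ZT08, and 335 without the 3 wild-type set I libraries.

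At ZT12, Tmc5 stood at 0.0303 ± 0.0429 against 14 ± 2.69 CPM, and Tead2 (0.667 ± 0.0854 to 11.2 ± 1.78 CPM, SD, n = 2, 4.05) and Igsf23 (3.90) rose. Nlrp12 (−7.66, SE 0.67) and Cyp4a10 (1067 ± 701 to 7.73 ± 4.24 CPM, −7.11) fell, and so did 8 of 18 female-biased genes and 6 of 29 interferon response genes. Wild-type ZT12 replicate 1 stood out in both lists, and without it 4 female-biased and 0 interferon genes fell by edgeR, while without wild-type ZT12 replicate 2 the counts were 8 and 15. Hamp2 (−5.67) was lost without either knockout replicate of ZT12 (edgeR adjusted p 0.0655 and 0.0936). In all 105 genes rose and 174 fell (279). The count was 72, 90 and 118 without wild-type replicate 1, knockout replicate 1 and knockout replicate 2 of ZT12, and 828 without the 3 wild-type set I libraries.

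At ZT16 Slc6a16 rose from 0.744 ± 0.512 to 14.4 ± 6.85 CPM (SD, n = 2, 4.25, SE 0.50). The histocompatibility gene H2-Bl (4.08) was lost without wild-type ZT16 replicate 1 (edgeR adjusted p = 0.116), and the immediate early gene Egr1 (3.26) without any of 10 single libraries (0.0505 to 0.246). Nlrp12 (−7.57), Cyp2c50 (677 ± 27.6 to 22.2 ± 1.99 CPM, −4.93) and Cyp2c54 (−4.80) fell. The female-biased list went the other way than at ZT12, with 3 higher and 0 lower by edgeR (median 1.5, against −1.63 at ZT12), and so did the interferon median (0.54, against −1.28), where 0 genes passed by edgeR. In all 97 genes rose and 152 fell (249), or 469 blocked by letter. The count was 71, 95 and 115 without wild-type replicate 1, knockout replicate 1 and knockout replicate 2 of ZT16, 568 and 509 without replicates 1 and 2 of wild-type ZT20, and 161 without the 3 wild-type set I libraries.

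At ZT20 Selenbp2 (51.1 ± 0.556 to 743 ± 113 CPM, SD, n = 2, 3.86) and Igsf23 (3.80) rose, and Nlrp12 (−8.72, SE 0.74) and Cyp4a10 (−6.82, SE 0.81) fell. Nuclear respiratory genes were lower in 15 of 78 cases and ribosomal protein genes in 8 of 82. Synm (3.27) was lost without wild-type ZT20 replicate 1 (edgeR adjusted p = 0.11) and the fatty acid hydroxylase gene Cyp4a14 (−4.90) without wild-type replicate 1 or either knockout replicate of ZT20 (0.123 to 0.317). In all 221 genes rose and 372 fell (593), or 2871 blocked by letter, and this time held the library with the highest r against GC content. The count was 63, 50 and 79 without wild-type replicate 1, knockout replicate 1 and knockout replicate 2 of ZT20 and 8111 without wild-type replicate 2. It was 1365 and 958 without replicates 1 and 2 of wild-type ZT04, 1259 without replicate 1 of wild-type ZT16, and 104 without the 3 wild-type set I libraries.

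At ZT24 Tmc5 had no counts in either wild-type library and 10.4 ± 0.291 CPM in the knockout (SD, n = 2), and Tead2 rose from 0.673 ± 0.23 to 6.39 ± 0.143 CPM (3.24, SE 0.29). Cyp4a10 (−6.47), Nlrp12 (−5.39) and Cyp2c54 (488 ± 11.8 to 12.9 ± 4.72 CPM, −5.24) fell. H2-Bl (4.51) was lost without wild-type replicate 2 or knockout replicate 1 of ZT24 (edgeR adjusted p 0.0541 and 0.11). In all 44 genes rose and 58 fell (102), with counts of 44, 48, 38 and 63 without each of the 4 libraries of ZT24 in turn, and 213 without the 3 wild-type set I libraries. No gene passed the interaction of genotype with time by edgeR (966 at an unadjusted p under 0.05), so the differences between the 6 counts were not shown gene by gene.

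Rhythms of a 24 h period were fitted in each genotype to ask which oscillations remained in the knockout. Those of the clock did. Arntl, the activator of the clock, peaked at ZT 22.0 with a peak to trough of 22.5-fold in wild type and at ZT 21.8 with 34.2-fold in the knockout. The repressor Nr1d1 peaked at ZT 6.73 and 6.45 (71.2-fold and 63.9-fold), Cry1 at ZT 19 and 18.1 (log2 amplitude 1.60 ± 0.12 and 1.5 ± 0.12, SE), Ciart at ZT 11 and 11.1 and Per3 at ZT 11.5 and 10.5. Of 19 clock genes 12 were rhythmic in wild type and 13 in the knockout, and of 14 outputs 12 and 11. Dbp had an 81.3-fold rhythm peaking at ZT 9.42 in wild type and none called in the knockout. The remaining Tef and Hlf counts were rhythmic in both genotypes, Tef with peaks at ZT 11.9 and 11.1 and Hlf at ZT 12.8 and 13.4.

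Among the genes with the smallest p in either genotype were Ppara, the fatty acid receptor gene, with an amplitude of 0.68 ± 0.06 in wild type and 0.37 ± 0.06 in the knockout (SE, peaks at ZT 9.78 and 10.8), and Upp2, a uridine phosphorylase gene with 13.3-fold and 6.7-fold rhythms. Cyp2g1 had 31.6-fold and 7.14-fold rhythms. Ccdc162 (amplitudes 0.62 and 0.84), Pnrc1 (1.06 and 1.10), Zbtb21 (0.59 and 0.76) and the elongase gene Elovl3 (2.0 and 2.08) were also among them. In total 1308 genes were rhythmic in wild type and 538 in the knockout (edgeR, 24 libraries), and 343 in both, against 46.6 if the calls were independent. Fitted on each genotype's own 12 libraries the order turned round, with 218 in wild type and 2633 in the knockout. In those 343 the median shift of the peak was 0.2 h (quartiles −0.485 and 1) and 288 peaked within 2 h. Wild-type peaks were most frequent from ZT 8 to 12 (390 genes) and ZT 20 to 24 (358), and knockout peaks in the same bins (111 and 158). The wild-type count was 2142 without wild-type ZT04 replicate 1, 841 without wild-type ZT12 replicate 1, 0 in set I alone (edgeR) and 818 in set P alone. The knockout count was 860 without wild-type ZT20 replicate 1, 1848 without the 3 wild-type set I libraries and 0 in set I alone (edgeR), so the lower count in the knockout is no test of a loss of rhythm.

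The difference in rhythm between genotypes was tested directly. The smallest p with the larger amplitude in wild type belonged to Lgals4 (0.78 with a peak at ZT 8.94 against 0.50 at ZT 17.9), Lonrf1 (0.85 against 0.32) and the protease gene Adamts7 (0.65 at ZT 20.7 against 0.50 at ZT 11.1), each with an edgeR adjusted p = 0.194. Fam124a and Srebf1, the regulator of lipid synthesis (both 0.305), Snx29 and St3gal6 (0.342), Grk5 (0.409), Foxo1 and Morc4 (0.441) followed. With the larger amplitude in the knockout stood the prion protein gene Prnp (0.33 with a peak at ZT 14.4 against 0.35 at ZT 0.81, 0.194), Rfx4 (0.303), Cela1 (0.305), the globin gene Hba-a1 (0.342), Rcan2 (0.359), Mthfd1l (0.409), Hbb-bs and Elovl3 (0.441), and Acnat2 and Hba-a2 (0.533). None passed, so 0 genes differed by edgeR, with 791 at an unadjusted p under 0.05, against 754.5 for independent and uniform p-values. With genotype labels reassigned among the libraries of each time, this number ran from 60 to 3109. The 754.5 is therefore no measure of chance in these libraries. DESeq2 called 28 and model choice by BIC 1968, a choice that on simulated data called mostly unchanged genes. Without the 3 wild-type set I libraries Prnp, Lonrf1 and Grk5 were called. Single libraries left out gave Prnp (without wild-type ZT04 replicate 1), Lgals4 (wild-type ZT08 replicate 2), Kifc1 (wild-type ZT12 replicate 2) or Prnp, Mthfd1l and Hlf (knockout ZT24 replicate 2). Of the 39 gene lists 0 held an excess of differing genes by Fisher's exact test, since no gene was called. Adjusted over the list alone, 5 of 7 erythroid, 3 of 21 nuclear receptor, 2 of 29 fatty acid synthesis, 2 of 15 T and NK cell genes and 1 each of the clock output, interferon, male-biased and monocyte lists passed.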

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

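The tests on genes that stand out in wild-type ZT12 were chosen after the result was seen, as were their limits of 0.67 and 80%, whereas the interaction of genotype with time was planned.

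For 9 genes of the lists given here the genotype difference changed with time, with the edgeR interaction p adjusted over the 860 list genes; adjusted over all genes none passed (0 called by edgeR, 966 at an unadjusted p under 0.05). CPM values are those of replicates 1 and 2. Most of the 9 were high in wild type at ZT12. Acot3, a thioesterase gene (adjusted p = 0.0215), stood at 97.3 and 35.5 CPM at wild-type ZT12, and at 20.5 and 10 CPM at knockout ZT16. Cux2, a transcription factor of the female-biased pattern (0.0215), stood at 43.2 and 12.3 CPM, and Cyp17a1, a steroid hydroxylase (0.0215), at 237 and 74.6 CPM. Slc22a26 (0.0272) stood at 43.7 and 12.9 CPM in wild type at ZT12 and at 31.9 and 13.7 CPM in the knockout at ZT16. Slc22a27 (0.0485) stood at 16.6 and 5.64 CPM and Cyp2c39 (0.0319) at 746 and 368 CPM at wild-type ZT12. Ces1g (0.0215) ran from 57.7 to 203 CPM in wild type and from 5.78 to 37.2 CPM in the knockout. Cox6b2 (0.0241) stood at 4.64 and 1.67 CPM at wild-type ZT24, at 0.431 CPM or less in the other wild-type libraries and at 3.71 to 9.94 CPM in the knockout. Igfbp1, a secreted binding protein of growth factors (0.0484), stood at 108 and 43.9 CPM in wild type against 6.97 and 7.43 CPM in the knockout at ZT04, and at 67.5 and 89.5 against 14.9 and 13.6 CPM at ZT24.

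In wild-type set I, 47 genes of at least 5 CPM were at least 3-fold higher at ZT12 than at any other time, among them Acot3, Cux2, the interferon-induced Ifit1 and Isg15, Myc and Pck1, and all 47 were highest at ZT12 in set P too, as were 85 of 90 (94.4%) in the partner library over all groups, which a shared time of day would also give, so this decides nothing about the animals. Of the 8 genes chosen in set P with a lower limit of 2 CPM, 8 stood out more in set I, which argues against an effect of the time of day of the same size in both libraries. For the 47 genes the excess in set P was a median 0.302 of that in set I, but genes chosen in set I have a smaller excess in set P by their choice, and in the 9 other groups the medians were 0.256 to 0.62, so this decides nothing either. Over all groups only 13 of the 50 genes chosen in set P stood out more in set I, and 4 of 9 did so at knockout ZT16. Whether the set P library holds RNA of the set I animal mixed with that of others, or 2 animals responded by different amounts, cannot be told apart, since nothing in the labels says how animals were assigned to libraries.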

How the results depend on the processing

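Leaving out libraries for their trend with GC content, the length slope and set P for the gene lists were chosen after seeing the data. Of 250 named results 202 were called, and 164 of these kept direction and side of the threshold under every setting chosen before the data were examined. All 250 kept both with a robust prior, 248 with RLE factors, 237 with the letter block, 228 with DESeq2, 218 without a filter, 216 without the 3 wild-type set I libraries of highest GC trend, 216 without all 6, 198 with the length slope and 189 with block and slope, and the 238 that passed a mean CPM of 1 kept both too. The letter block moved no count by over 1.5 times beyond those given. Changes of sign were Clock −0.35 and Rora −0.37 with the length slope (Rora −0.29 with block and slope), and for Prnp, difference in log2 amplitude, wild type minus knockout, 0.0587 without wild-type ZT04 replicate 1 and 0.0283 without the 3 libraries (range without single libraries −0.0633 to 0.0587). Depth limits genes near 1 CPM, and 2 libraries per group limit single times. Fewer genes pass a stricter threshold or tested fold by construction, and fewer samples make smaller sets weaker; otherwise the cause was not tested. Counts below run averaged, ZT04, ZT08, ZT12, ZT16, ZT20, ZT24 unless named.

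At a threshold of 0.01 they were 1885, 62, 70, 120, 86, 72 and 47, with 469 and 230 rhythmic genes in wild type and knockout, and with a tested fold of 1.5 they were 408, 76, 78, 119, 94, 75 and 62. With only the 4 libraries of a time edgeR gave 0 at ZT04, ZT16 and ZT20 (1145, 1397 and 883 at an unadjusted p under 0.05), 78 at ZT12 and 192 at ZT24. Without a filter the 6 times gave 1079, 416, 632, 1533, 3130 and 343, with 72 differing rhythms, 16 lists and 8 lists for rhythm. Blocked counts were 7898 averaged, 370 at ZT04, 469 at ZT16 and 2871 at ZT20. DESeq2 gave 349, 214, 430, 1236 and 169 at ZT04, ZT08, ZT16, ZT20 and ZT24, 995 knockout rhythms and 28 differing ones. Set P alone gave 1963 averaged and 818 wild-type rhythms, and set I alone 0 in wild type and 0 in the knockout by edgeR (1715 and 644 unadjusted). Rhythms fitted on a genotype's own libraries numbered 218 and 2633, knockout rhythms with time as a factor 340, and BIC chose 1968 differing ones. With an estimated correlation camera called 0 lists. Fry, with all 24 libraries, passed every list that camera called with the preset correlation (fry adjusted p 3.3e-06 to 0.0205). Because fry does not compare a list with other genes, and 5007 of 15090 genes were called, these passes do not strengthen the camera calls. It also passed lists that camera did not. Among these were bile acid synthesis (fry adjusted p = 0.000238), clock outputs (0.000717) and the core clock (0.0326) downward, and transporters (0.00141) upward. Acute phase (0.71) and cholesterol synthesis (0.614) were among the lists that passed neither.

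Without the 3 libraries the counts were 3295 averaged, then 335, 828, 161, 104 and 213 from ZT08 to ZT24, 1848 knockout rhythms and 3 differing ones. Without all 6 they were 2855 averaged, 355 at ZT20, and 762 and 2739 rhythms. With the length slope they were 2138, 314, 428, 1086, 490, 236 and 332, with 3364 and 2339 rhythms and 6 differing (Prnp, Lgals4, Vac14, Hlf, Cela1 and Kifc1). With block and slope they were 1538, 308, 464, 1216, 452, 162 and 359, with 3433 and 2499 rhythms and 2 differing (Prnp and Vac14). Leaving out 1 library at a time, where a lone sample is assumed to vary like the other groups, gave 3359 to 9084 averaged, 41 to 399, 46 to 195, 72 to 406, 71 to 568, 50 to 8111 and 38 to 130 at the 6 times, 841 to 2142 and 390 to 860 rhythms, 0 to 3 differing, 9 to 11 lists and 0 to 0 lists for rhythm.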

Other observations

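The tests on genes near the deleted loci and those with the length slope were chosen after the result was seen, and those on matched lists and on other splits of the samples were written before it. The splits that part letter pairs were added after seeing the data, though before their own result.

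Some single libraries held bursts of genes. Wild-type ZT04 replicate 2 was rich in ribosomal and small structural RNA, with 21870 CPM of CT010467.1 against at most 433 CPM in the other wild-type set P libraries, and 9042 CPM of Lars2, 2219 CPM of the mitochondrial ribosomal RNA mt-Rnr1, 230 CPM of n-R5-8s1 and 69.6 CPM of Rn7sk. Wild-type ZT08 replicate 2 held acute-phase and neutrophil transcripts, with 2220 CPM of Saa1 and 2071 CPM of Saa2 against 169 and 49.4 CPM in replicate 1. In that library the neutrophil genes S100a8 (16.3 against 2.69 CPM), S100a9 (22.9 against 2.86 CPM) and Ltf (8.84 against 0.63 CPM) were high, with Lcn2 at 168 against 54.4 CPM.

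Over time, the interaction of genotype with time, adjusted over the list alone, passed in 12 of 18 female-biased genes, 11 of 29 interferon response genes and 5 of 7 erythroid genes. Ifit1 (0.0498), Mx1 (0.0406) and Irf7 (0.0498) were among the interferon genes, and Hba-a1 (0.0148) and Alas2 (0.0339) among the erythroid ones. None of these passed adjusted over all genes (0 by edgeR, 966 at an unadjusted p under 0.05). Genes within these lists were correlated (estimated at 0.228, 0.486 and 0.472 in that order), so the counts are not of independent genes. Adjustment over a list alone also does not cover the search over 39 lists. The interferon median at ZT12 was −1.28, and −0.48 without wild-type ZT12 replicate 1.

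Within 10 Mb of Dbp, 35 of 145 genes were called at 2-fold or more (24.1%), against 618 of 14438 outside the windows of the 3 deleted genes (4.28%, Fisher's exact p = 1.19e-16, two-sided), among them Tead2, Ftl1, Saa1, Saa2, Saa3, Cd33 and Car11, and none of 10000 random runs of as many neighbouring genes reached this (highest 26). In set P alone 21.4% of genes near Dbp were called against 2.67% elsewhere, which argues against the trend of wild-type set I as the cause. Set P also differed between genotypes in its trend with GC content (mean r −0.0707 in wild type, −0.3 in the knockout). The length and GC content of the genes near Dbp were not matched, so a length and GC trend in general is not excluded. DNA linked to the targeted Dbp allele, such as that of another strain carried along by selection, is a candidate explanation, and it may account for part of the changes of these genes. Tef had 15 of 280 and Hlf 8 of 215 such genes, numbers that 25.3% and 52.9% of random runs reached, so an excess around these loci was not seen. The rest of chromosome 7, where Nlrp12 and Tmc5 lie, held 92 of 1041 such genes (8.84%, other chromosomes 3.93%). Whether linked DNA accounts for any of these was not tested. Action of Dbp on its neighbours stays open too, since no reads that would show a strain were analysed here.

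Ribosomal protein and nuclear respiratory genes, which are short, were lower in the knockout by medians of −0.30 and −0.36. Against 10000 lists matched on length, GC content and expression, 0% were as low as the respiratory list with all libraries and 0% in set P alone (−0.18, matched −0.07). Both lay under the limit of 2.5% set beforehand. With the letter block and length slope its median was −0.11 (quartiles −0.18 and −0.04). Matched genes were drawn independently, without the correlation within the real lists, estimated at 0.528 for respiratory and 0.498 for ribosomal genes. The matched medians may therefore vary too little, and the shares do not decide whether the length and GC trend of the libraries is the whole cause. For the ribosomal list the share was 0.02% in set P alone (−0.14, matched −0.08), under the limit but open to the same doubt. With all libraries it was 2.47%, too close to the limit of 2.5% to decide. With block and slope the ribosomal call ended (camera adjusted p = 0.525, against 9.52e-08). Its median shrank from −0.30 (quartiles −0.37 and −0.15) to −0.03 (−0.09 and 0.02), so the trend stays open for this list. Matched genes fell too, by medians of −0.25 and −0.23, so the trend may account for part of the size, and a lower level of both complexes stays open, since neither list passed with an estimated correlation (adjusted p = 0.633 and 0.596).

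Other splits of the samples were drawn 100 times each, the real one included. Chance can be excluded for the averaged count, where the real split gave 5007 genes and the highest other 174 (1 of 100 as large), and among splits that part as many letter pairs, where the highest other gave 3253 (1 of 100). In those, 5 other splits gave over 400 genes, and all 5 kept the 3 wild-type set I libraries with the highest GC trend on 1 side and at least 10 of the 12 wild-type libraries together, while splits that parted the 3 gave at most 70. Chance can be excluded for rhythm in the knockout (538 genes, highest other 2, 1 of 100). In wild type 4 of 100 draws, the real one included, gave at least the real 1308 genes, which is under the limit set beforehand. The others of these gave 2559, 3957 and 5872 genes, which points to a structure of the wild-type samples and leaves chance not firmly excluded. For the difference in rhythm chance cannot be excluded, but with a real count of 0 every split is as large by construction (100 of 100), so this test decides nothing. The highest other count was 1, and among the splits that part letter pairs it was 39, with 24 as the next.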
